A study of Mus musculus with 6 samples.

How the data were processed

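Gene expression was measured in satellite cells, the stem cells of skeletal muscle, sorted from male C57BL/6 mice. Cells carrying integrin alpha7 and CD34 were kept, and cells carrying CD31, CD45, CD11b or Sca1 were removed, per the labels. There were 3 young samples (3, 2 and 3 months for replicates 1, 2 and 3) and 3 adult samples (all 6 months). RNA was amplified with a whole transcriptome method for small cell numbers and labelled with Cy3, per the labels' protocols. The labels call the samples biological replicates and do not say how many mice stood behind each.

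Each sample was hybridised to 1 single-colour Agilent array of 62976 spots. The spots were read with Feature Extraction 10.7.3.1, per the file headers, and the deposited intensity values were the background-subtracted and detrended signal, the mean pixel signal and the median local background of each spot. Per the file headers, no scaling between arrays was applied to these intensities, and signals not above background were replaced by surrogate values. All 6 arrays lay on 1 slide and were scanned together, so slide and scan could not act as batches. The deposited series matrix held log2 values whose making is not given in the sources used here. In each column its median was 7.56, and it differed by at most 0.000106 from a normexp background correction (offset 50) with quantile normalization computed from the mean and background signals. Its scale, centring and direction were thereby settled from the values.

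The 3671 control spots and spots marked as outliers were left out, no spot was saturated, and spots of 1 probe were averaged, giving 55681 probes. The main values were log2 of the processed signal minus each array's 75th percentile. Probes well above background on at least 3 arrays were kept. Each gene was represented by the probe with the highest mean over the 6 arrays, which gave 32077 genes, unnamed transcripts included. Symbols were updated with the GRCm38.p6 gene table through accessions (26300 probes), current symbols (2044 probes) or older symbols (355 probes), and 26982 probes kept the name in the files. Probe positions are those of the files, on mouse build mm9.

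Adult and young were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The files were read with the R package data.table, version 1.17.8. Positive values mean higher in adult. A probe not well above background on any array of a group has only a bound there. The bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The 33 gene lists were tested with camera (correlation preset at 0.01, at least 5 measured members, adjustment over the lists), and beside it with an estimated correlation and with fry. The position of each list's median was also found among 10000 random lists of the same size, drawn from all genes and matched on mean level in 50 bins.

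The design, the 33 lists, the rule for naming genes and the alternatives were set before the data were examined, except cyclic loess, the restriction to genes above the 75th percentile, the level-matched lists and a second pericyte list with its variant, which were added after. The rule took the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, leaving out clone, predicted and accession names. It added the genes of the sorting gate with Pax7, Myf5, Myod1, Cdkn2a and Cdkn1a, and up to 4 members with the smallest p of each list. Kcnj8, Pdgfrb, Acta2, Abcc9, Rgs5, Higd1b, Ndufa4l2, Dux, Vmn1r124, Mef2c, Myh2, Vtn and Tagln were picked out after their values were seen. The rule also takes Kcnj8, Acta2, Higd1b and Ndufa4l2. Alternatives covered scaling, background correction, the filter on dim probes, the choice of probe, the variance model, array weights, blocks by replicate number and by array row, and leaving out each array. A slide block had nothing to estimate, with a single slide.

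The fit was tested on simulated arrays with the levels and spreads of 32056 genes. With 200 changed genes, 0.299% of changes of 1 log2 unit, 41.8% of 2 units and 73.0% of 4 units were called, and 4.26% of all calls were false. With 9000 changed genes the shares were 54.1%, 81.7% and 95.9%, with 3.93% false. In simulated lists of independent genes, each of the 60 lists shifted by -0.5 was called, as were 0.364% of 549 unshifted lists. Those simulations held no correlation between genes. The number of arrays limits the precision of every value.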

Results

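The data covered satellite cells in 3 samples from young and 3 from adult male mice, 1 array per sample. The comparison asked which genes differ between muscle stem cells of adult and of young animals. Of the 55681 probes, 41531, 45929 and 43076 were well above background on young arrays 1, 2 and 3, and 47585, 49763 and 49965 on adult arrays 1, 2 and 3. Correlations across genes lay between 0.944 and 0.960 within groups and between 0.849 and 0.933 between groups. The first principal component held 66.6% of the variance and parted the groups. Young replicate 2, the only sample of 2 months, lay nearest to the adult arrays, at -46.1. The other young arrays lay at -126.5 and -177.0, and the adult ones at 100.6 to 142.0. Of the young arrays, replicate 2 also had the most probes well above background and the highest 25th percentile of processed signal (31.5 against 18.8 and 22.1).

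Several genes of muscle differentiation were lower in adult than in young satellite cells, as were some genes of cell division described further below. Myog, a transcription factor of muscle differentiation, stood at -3.82 ± 0.37 in adult and 1.43 ± 0.29 in young (log2 relative to the array's 75th percentile, SD, n = 3 each), and so was 37.8-fold lower (log2 difference -5.24 ± 0.27 SE, limma adjusted p = 0.00842). Mymk, a membrane protein needed for myoblast fusion, fell by 3.72, and Cdkn1c, an imprinted inhibitor of the cell cycle, fell by 3.95 (adjusted p = 0.00842 for both). The probes of these genes lie on mm9 chromosome 1 from 136188874 to 136188933 (Myog), chromosome 2 from 26917594 to 26917653 (Mymk) and chromosome 7 from 150644753 to 150644812 (Cdkn1c). Actc1, an actin of heart and embryonic muscle, was also lower in adult (adjusted p = 0.0252), by an uncertain size, since it was well above background on 2 of 3 adult arrays.

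Over all genes, 9139 of 32077 passed the threshold, 6430 higher and 2709 lower in adult. At an unadjusted p under 0.05 there were 15438. The groups did not overlap in 55.6% of genes, where chance gives 10%. The direction depended on level and scaling. The median of all genes lay at 0.30 here, at -0.06 with quantile normalization (2873 higher, 2752 lower) and at -0.24 with median scaling (3446 higher, 8812 lower). Some list medians below are therefore also given relative to all genes. The 17414 named genes had a median of -0.03 (2571 higher, 2119 lower), and 13286 unnamed and lincRNA transcripts 0.60 (3460 higher, 507 lower). The lists hold named genes, so values relative to all genes lie lower than they would relative to named genes. Camera likewise compared each list with all other genes, unnamed ones included. The split was 7883 higher and 1786 lower when scaled on probes above background on all arrays, 4430 and 4093 with the series matrix values, and 3130 and 2146 with cyclic loess, which was chosen after the data were seen. In the 8020 dimmest genes the median difference was 1.44, with 2567 higher and 63 lower, and in the 8019 brightest it was -0.31, with 828 higher and 1517 lower. Of 974 olfactory and vomeronasal receptor genes, 484 were higher by limma and 0 lower (754 at an unadjusted p under 0.05), with a median of 2.19. With probes above background on all 6 arrays only, 376 receptor genes were left, with a median of 1.63 (272 higher, 0 lower). The size of this rise is therefore uncertain. The number of calls changed with most arrays left out: without young replicates 1, 2 and 3 they numbered 1355, 7680 and 2377, and without adult replicates 1, 2 and 3 they numbered 484, 760 and 296.

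**Figure D1:**
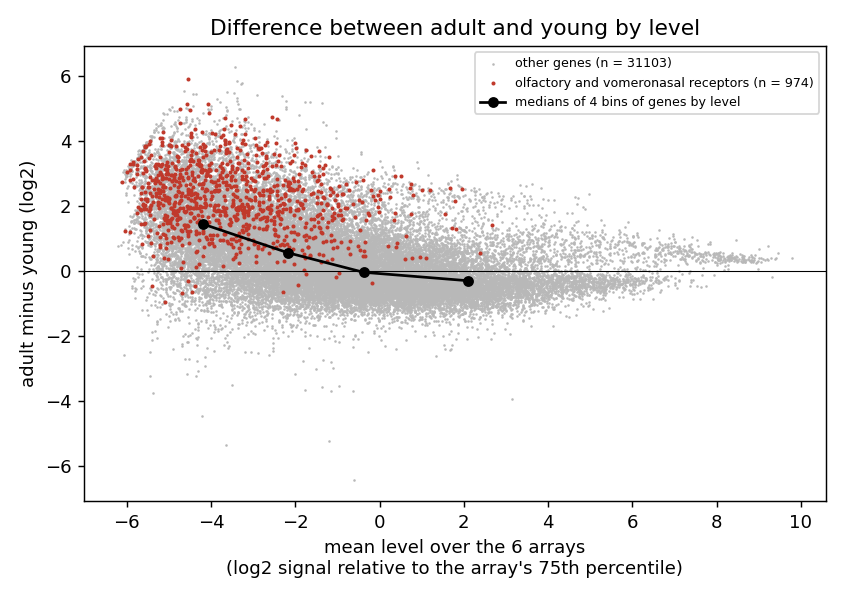
Each point is a gene, with its mean log2 level over the 6 arrays on the x axis and the adult minus young log2 difference on the y axis. Olfactory and vomeronasal receptors are red, and the black line joins the medians of 4 bins of genes by level, from 1.44 in the dimmest to -0.31 in the brightest.

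Among the 10 largest falls, besides those above, H2ac4 (a histone H2A gene) was at least 19.9-fold lower in adult (adjusted p = 0.0153) and Cdca3, a gene of cell division, at least 3.50-fold lower (adjusted p = 0.0218). Neither was well above background on any adult array. Kif23, a kinesin of cytokinesis, was 12.9-fold lower (adjusted p = 0.0140) and Gpr50, an orphan receptor, 11.9-fold lower (adjusted p = 0.0271). Mki67, a proliferation marker, was 12.9-fold lower by its brighter probe (adjusted p = 0.0151), but its other probe differed by 0.07 ± 0.53 SE. Chn2 was at least 9.98-fold lower by its brightest probe (adjusted p = 0.00898) but its other probes differed by -3.80 and 2.94. The genes of the 10 largest rises were well above background on at most 2 of 3 young arrays. Tyrobp, an adaptor protein of myeloid cells, was at least 31.2-fold higher in adult (adjusted p = 0.0157), the olfactory receptor Olfr45 at least 13.7-fold (adjusted p = 0.0135) and the peptide receptor Qrfpr at least 12.7-fold (adjusted p = 0.00914). A second Qrfpr probe differed by 1.95 ± 1.20 SE. The other 7 were Map3k21, Pramel13, Rnase2b and Oprk1, well above background on 1 of 3 young arrays, and Prss32, Cyp2a22 and Mgat4f, well above it on 2 of 3, so the sizes of these rises are uncertain.

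Of the 6 genes of the sorting gate only Itga7 passed the threshold by the probe used for each gene. Itga7, which encodes integrin alpha7, was 2.11-fold lower in adult (0.84 ± 0.22 against 1.92 ± 0.05, SD, adjusted p = 0.0230). Cd34 differed by -0.18 ± 0.21 SE and Ly6a (Sca1) by 0.12 ± 0.77 SE. Pecam1 (CD31) differed by -0.81 ± 0.48 SE (adjusted p = 0.222) and Ptprc (CD45) by 0.49 ± 0.34 SE (adjusted p = 0.278). Itgam (CD11b) differed by 0.39 ± 0.28 SE by its brightest probe (adjusted p = 0.304), whose mean level was 8.37. Its other probes, at mean levels of -0.88 and -0.99, differed by 1.46 ± 0.34 SE and 1.46 ± 0.49 SE (limma unadjusted p = 0.00506 and 0.0233). The result for Itgam therefore depends on the probe. Pax7, the transcription factor that marks satellite cells, differed by -0.34 ± 0.25 SE (adjusted p = 0.304), Myf5 by -0.37 ± 0.22 SE (adjusted p = 0.222) and Myod1 by -0.64 ± 0.22 SE (adjusted p = 0.0699). For the senescence genes, Cdkn2a differed by 1.56 ± 0.84 SE (adjusted p = 0.186) and Cdkn1a by -0.07 ± 0.24 SE (adjusted p = 0.820), with another Cdkn1a probe at 2.22 ± 0.62 SE.

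**Figure D2:**
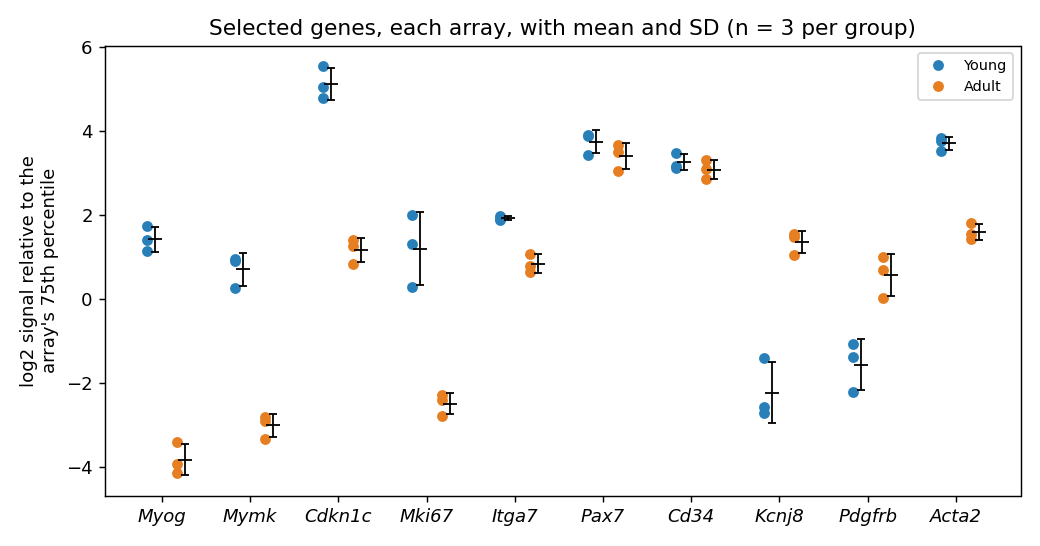
Points are single arrays, and bars give the mean and SD of 3 arrays per group, on a log2 scale relative to each array's 75th percentile. Myog, Mymk, Cdkn1c, Mki67, Itga7 and Acta2 lie lower in adult, Kcnj8 and Pdgfrb lie higher, and the groups overlap for Pax7 and Cd34. Mki67 is shown by its brighter probe, and its other probe differed by 0.07 ± 0.53 SE.

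Of the 33 lists, camera placed 18 past the threshold, 16 lower and 2 higher in adult. These calls rest on the preset correlation: with an estimated correlation 0 lists passed (3 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 12 of the 18 in the same direction and 3 others, those of mural cell markers, adipocyte markers and secreted senescence-associated factors. It did not call the lists of the cell cycle, immediate early and heat shock genes and Polycomb and chromatin (fry adjusted p = 0.0852 each), oxidative stress defence (0.123), myofibre markers (0.197) and TGF-beta and BMP (0.258). Of the 18, 14 stayed past the threshold with any single array left out, and those of CDK inhibitors, TGF-beta and BMP, immediate early and heat shock genes and myofibre markers did not.

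In the myogenic commitment list, 8 of 18 measured members were lower, 1 higher and 9 did not pass, and 11 were lower adjusted over the list alone. Its median was -1.32, or -1.62 relative to all genes (camera adjusted p = 4.7e-05; adjusted p = 0.271 with an estimated correlation). It passed in 20 of 22 alternatives, with adjusted p from 6.62e-06 to 0.630. Beside Myog and Mymk, which stayed past the threshold with any array left out, Chrna1 and Chrnd, subunits of the muscle acetylcholine receptor, were 5.46-fold and 5.67-fold lower, while Mef2c, a transcription factor of muscle, was 3.18-fold higher and was named after its value was seen. In the cell cycle list, 6 of 23 members were lower, 1 was higher and 16 did not pass, and 7 were lower adjusted over the list alone. Its median was -0.82, or -1.12 relative to all genes (camera adjusted p = 0.000154; adjusted p = 0.424 with an estimated correlation). Mcm2, a subunit of the replication helicase, was 3.95-fold lower and Birc5 (survivin) 4.40-fold lower, while Tyms, which makes thymidylate, was 2.49-fold higher. Of 20 markers of myofibres, the mature muscle cells, 7 were lower, 1 was higher and 12 did not pass, in both counts (median -0.10, camera adjusted p = 0.0459; adjusted p = 0.424 with an estimated correlation). Differences were positive for 10 markers and negative for 10, and the list did not pass in 12 of 22 alternatives. Ryr1, the calcium release channel of muscle, was 2.32-fold, Acta1, skeletal muscle actin, 2.29-fold and Atp2a1, a calcium pump, 2.13-fold lower. Myh2, a myosin heavy chain named after its value was seen, was 2.55-fold higher.

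Genes of the mitochondrial respiratory chain were lower as a group. In the oxidative phosphorylation list 33 of 38 members were lower and 5 did not pass, with 37 lower adjusted over the list alone and a median of -1.05, or -1.35 relative to all genes (camera adjusted p = 4.92e-18; adjusted p = 0.394 with an estimated correlation). Ndufa4 was 4.01-fold, Cox5a 3.74-fold and Uqcrq 3.05-fold lower, beside the 7 lower myofibre markers. In glycolysis 6 of 18 members were lower, in both counts, and 12 did not pass. The glycolysis median was -0.51 (camera adjusted p = 0.000491; adjusted p = 0.394 with an estimated correlation). Pgam1 was 2.02-fold and Eno1 1.98-fold lower. Of 43 ribosomal protein genes 4 were lower and 39 did not pass, and 0 passed adjusted over the list alone. Their median was -0.39 (camera adjusted p = 6.89e-08; adjusted p = 0.424 with an estimated correlation), and Rpl27 was 1.75-fold lower.

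In the extracellular matrix list 18 of 30 members were lower and 12 did not pass, with 21 lower adjusted over the list alone. The median was -1.02, or -1.32 relative to all genes (camera adjusted p = 8.08e-10; adjusted p = 0.271 with an estimated correlation). The basement membrane genes Lamc1, Col15a1, Col4a1 and Col4a2 were 2.60-fold, 2.73-fold, 2.05-fold and 2.21-fold lower. Of 5 tenocyte markers, genes of tendon cells, 4 were negative and 1 passed, Scx, a tendon transcription factor, which was 2.08-fold lower (adjusted p = 0.0252). That list did not pass camera (median -1.31, adjusted p = 0.120), and its median lay at percentile 0 of random lists of the same level. Among imprinted growth genes 8 of 19 were lower and 11 did not pass, with 11 lower adjusted over the list alone. The median was -0.70, or -1.01 relative to all genes (camera adjusted p = 4.17e-06; adjusted p = 0.367 with an estimated correlation). Beside Cdkn1c, Dlk1 was 5.26-fold, Mest 4.27-fold and Grb10 2.09-fold lower. In the satellite cell identity list 10 of 20 members were lower and 10 did not pass, with 11 lower adjusted over the list alone. The median was -0.64, or -0.95 relative to all genes (camera adjusted p = 3.23e-05; adjusted p = 0.424 with an estimated correlation). Msc, Megf10 and Itgb1 were 2.76-fold, 2.06-fold and 1.84-fold lower.

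**Figure D3:**
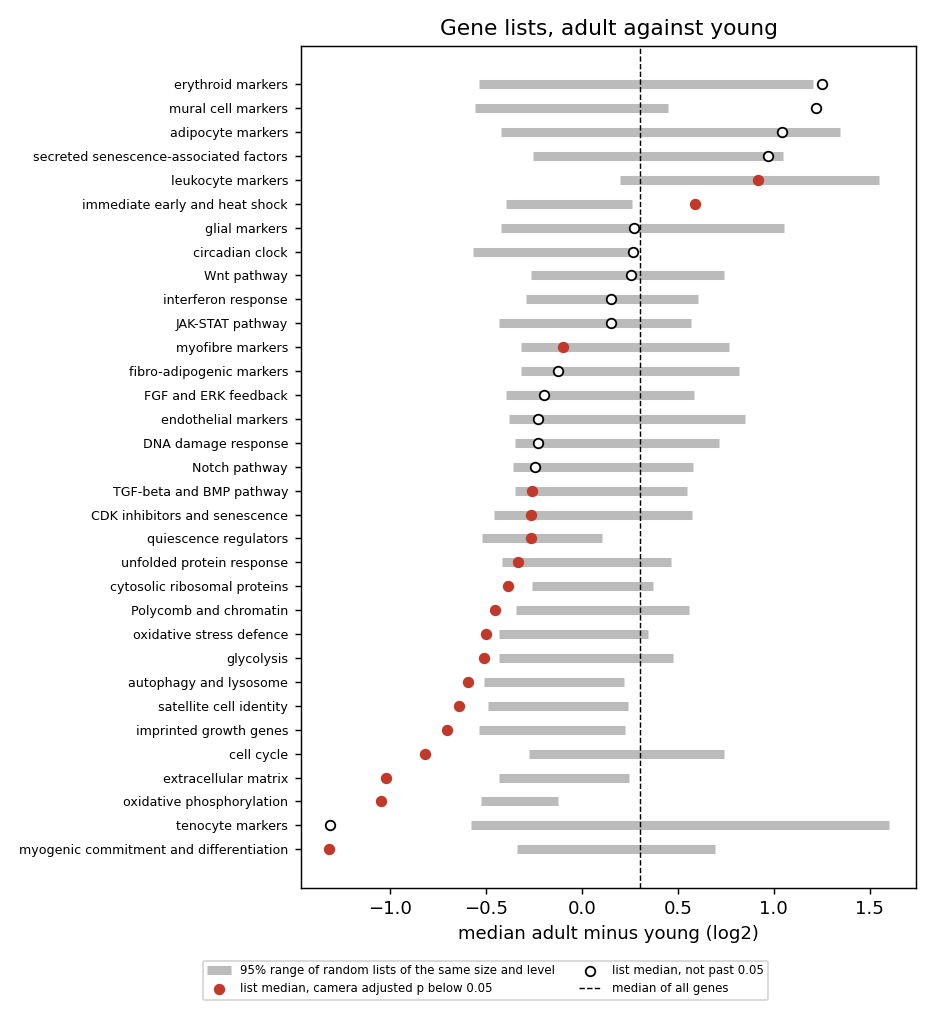
Dots give the median adult minus young log2 difference of each of the 33 lists, filled where camera's adjusted p was below 0.05. Grey bars give the 95% range of random lists of the same size and level, and the dashed line is the median of all genes, 0.30.

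The lists higher in adult were immediate early and heat shock genes and leukocyte markers. Of 32 immediate early and heat shock genes 29 had positive differences, 3 passed and 0 passed adjusted over the list alone. Their median was 0.59, or 0.29 relative to all genes (camera adjusted p = 0.0210; adjusted p = 0.547 with an estimated correlation). With camera under median scaling the adjusted p was 0.149, and over all alternatives it ranged from 2.11e-05 to 0.547. Atf3, a stress-induced transcription factor, was 2.03-fold higher and Nr4a2 3.04-fold higher. Of 18 leukocyte markers 4 were higher and 14 did not pass, with 3 higher adjusted over the list alone. Their median was 0.92, or 0.61 relative to all genes (camera adjusted p = 0.0255; adjusted p = 0.394 with an estimated correlation), and lay at percentile 60.97 of random lists of the same level. The leukocyte list passed in 17 of 21 alternatives, with adjusted p from 0.00597 to 0.394. Adgre1, a macrophage receptor, was 4.98-fold higher.

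Markers of other cell types went in different directions. Of 12 mural cell markers, genes of pericytes and vascular smooth muscle, 6 were higher, 1 was lower and 5 did not pass, in both counts, and the list did not pass (median 1.22, camera adjusted p = 0.0782). It passed in 9 of 22 alternatives, with adjusted p from 0.00410 to 0.499, among them quantile normalization, the series matrix values (0.00410) and fry (0.0382). Kcnj8, a potassium channel subunit, was higher by 3.58 (log2, 0.39 SE) and Pdgfrb, a receptor of pericytes, 4.38-fold higher, while Acta2, smooth muscle actin, was 4.30-fold lower. Of 8 adipocyte markers 5 were higher, among them Adipoq (8.78-fold) and Cfd (4.74-fold), and the list did not pass with camera (adjusted p = 0.0782; fry adjusted p = 0.00761; range over the alternatives 0.00761 to 0.424). Of 14 endothelial markers 1 was higher, and of 7 erythroid markers 0 passed. Of 16 fibro-adipogenic markers 5 were higher and 3 lower.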

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

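The array carries 350 control spots for the viral E1A sequence, which serve as spike-in controls and enter no comparison above. Their mean signal above local background was 322.0 on adult array 1, 215.7 on adult array 2 and 151.0 on adult array 3. On the young arrays the mean lay between 130.6 and 135.5, below that of each adult array. The medians did not part the groups, at 37.7, 28.3 and 20.7 on adult arrays 1, 2 and 3 and 20.2 to 21.3 on the young arrays. Whether spike-in RNA was added is not given in the sources used here.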

How the results depend on the processing

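The cyclic loess scaling, the restriction to genes above the 75th percentile and the percentile among level-matched lists were chosen after the data were seen. Quantile normalization gave 5625 calls (2873 higher, 2752 lower), of which 2712 and 1565 were also called in the same direction above. Scaling on probes above background on all arrays left 1786 lower, and median scaling gave 3446 higher and 8812 lower. Lower calls numbered 4109 with normexp, 4093 with the series matrix values and 4433 with trend and robust moderation. Cyclic loess gave 5276 calls, 3130 of them higher, and the restriction to bright genes, which tests fewer genes, gave 5602 calls, 1902 of them higher, and 5 lists. With array row as a block there were 5971 calls, 1201 of them lower. Camera with an estimated correlation called 0 lists (3 at an unadjusted p under 0.05), and fry called 15. The cause of these changes was not tested. Leaving out 1 array gave 296 to 7680 calls, 274 to 6419 higher and 22 to 1261 lower, with fewer samples in each fit, and 15 to 20 lists. Named genes past the threshold numbered 127, among them Pdgfrb, Abcc9, Rgs5, Dux and Vmn1r124, which entered only after their values were seen. Of the 127, 9 stayed past the threshold with any array left out: Myog, Mymk, Cdkn1c, Chn2, Acta2, Adipoq, Mmp13, Olfr45 and Qrfpr. The leukocyte gene H2-Aa, at 1.15 above, turned to -0.077 with quantile normalization, -0.0021 with the series matrix values and -0.072 with cyclic loess. The replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.0024, -0.094 and -0.14. With the replicate block, limma called 0 genes, 0 higher and 0 lower, with 12727 at an unadjusted p under 0.05, and 17 of the 18 lists stayed past the threshold. A slide block could not be run with 1 slide. Signal over background limits the dim genes, where the groups differed most.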

Other observations

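Some secreted and fibro-adipogenic genes not described above were higher in adult cells. Of 17 measured genes of the senescence-associated secreted list 5 were higher and 12 did not pass, and the list did not pass (camera adjusted p = 0.120; fry adjusted p = 0.0113; range over the alternatives 0.0113 to 0.630). Mmp13, a collagenase, was at least 1.79-fold higher (adjusted p = 0.00851) and Il1b 2.96-fold. Mmp3 was also higher (adjusted p = 0.0202), and was well above background on 1 of 3 young arrays. Among fibro-adipogenic markers Pi16 was 2.56-fold higher. The lists of autophagy (median -0.60), Polycomb and chromatin (-0.45), oxidative stress defence (-0.50), unfolded protein response (-0.33), quiescence regulators (-0.26), CDK inhibitors and senescence (-0.26) and TGF-beta and BMP (-0.26) also passed camera on the lower side, with adjusted p from 0.394 to 0.464 with an estimated correlation. Of these 7, the last 4, and myofibre markers, lay within the central 95% of random lists of the same level.

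Lists that did not pass camera were Notch (median -0.24, camera adjusted p = 0.0992), DNA damage (-0.23, 0.0721), FGF and ERK feedback (-0.20, 0.148), interferon (0.15, 0.899), glial markers (0.27, 0.899), erythroid markers (1.25, 0.311) and fibro-adipogenic markers (-0.12, 0.325). For the lists of Wnt (0.26, 0.311), JAK-STAT (0.15, 0.899) and circadian clock genes (0.27, 0.899) the median and mean were positive and the direction of camera, which compares with the other genes, was down. For endothelial markers the median was -0.23, the mean 0.05 and the direction of camera down (adjusted p = 0.733).

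Of the tests below, those on array background, scaling and level-matched lists, the stricter class of junction probes and the pericyte list with Notch3, were chosen after the results were seen.

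Of 974 olfactory and vomeronasal receptor genes, 484 were higher in adult by limma and 0 lower (754 at an unadjusted p under 0.05). Raised background, as far as the control spots measure it, and scaling, as far as quantile normalization tests it, were argued against as the whole cause. The rise of negative control spots was 0.0441 of the receptor probes' rise. These are unlike measures: mean signal with no background subtracted for the controls, and background-subtracted processed signal for the receptors. Quantile normalization left the receptor median 1.32 above all genes (200 higher, 5 lower). Scaling by 1 factor per array moves all genes alike, so median scaling could not change the main value of 1.88. With normexp the receptor median lay only 0.69 and with the series matrix values 0.53 above all genes, so the size of the rise depends on the processing. Genomic DNA carried into the amplified material was tested in 2 ways fixed beforehand, and these disagreed. They used different sets of dim probes, and neither was confined to receptor genes. Dim probes lying in 1 piece of the genome rose by 0.070 more than 427 probes crossing exon junctions (95% bootstrap interval -0.12 to 0.19; 0.092 with a stricter class of 402), below the 0.25 set as the least that DNA would give, whereas dim unnamed X-linked probes rose less than autosomal ones, by -0.27 (interval -0.40 to -0.14), as a single X in males would give. Junction probes were told by the span of their coordinates and the place of the junction was not read, so DNA could still have paired with part of them. Among the young arrays the receptor median was highest for replicate 2, the sample of 2 months (-3.72 against -4.58 and -5.35). It therefore did not rise with age within that group. Genomic DNA, amplification, RNA quality and age stay open.

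Bright genes were in general lower in adult, and so were several lists. A shift set by level alone, the same for named and unnamed genes, was argued against as the whole cause, within the limits given below. The list medians lay at percentile 0 of level-matched lists for oxidative phosphorylation, extracellular matrix, myogenic commitment, cell cycle and ribosomal proteins. They lay at 0.05 for imprinted growth genes and at 0.11 for satellite cell identity. The medians of level-matched lists were themselves negative for oxidative phosphorylation (-0.35), imprinted growth genes (-0.25), satellite cell identity (-0.24) and extracellular matrix (-0.20), but not for ribosomal proteins (0.0080), myogenic commitment (0.15) and cell cycle (0.21). Those percentiles treat genes as independent, as camera's preset correlation nearly does. For these lists the estimated correlation ran from -0.01 (myogenic commitment) to 0.51 (ribosomal proteins). The random lists were drawn from all genes, with unnamed and lincRNA transcripts (median 0.60) beside named genes (median -0.03). The percentiles therefore cannot part a fall of these lists from a difference between named and unnamed genes of the same level. Age parts the same 3 and 3 samples and stays open, as does amplification, whose batches are not given in the sources used here.

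Mural cell markers had a median at percentile 100 of level-matched lists. A candidate explanation is that more pericytes passed the adult sort, although cells lacking integrin alpha7 or CD34 would have been removed by it, and the lineage markers do not name pericytes. A second list of 17 pericyte genes, sharing no gene with the others and tested without Notch3, whose value (-0.15 ± 0.20 SE) had been seen, had 14 measured members, 6 higher and 0 lower by limma, with a median at percentile 98.84 (98.91 with Notch3). Of the 14, 13 were above background on all young arrays, which does not decide the question, since the young sorts could also hold some pericytes. Higd1b (2.00 ± 0.29 SE) and Ndufa4l2 (1.84 ± 0.24 SE) of the mural list, and Abcc9 (2.37 ± 0.52 SE) and Rgs5 (1.87 ± 0.41 SE), were higher in adult. However, Vtn (0.02 ± 0.18 SE), Tagln (-0.03 ± 0.18 SE) and Acta2 (-2.10 ± 0.20 SE) did not rise. All of these genes were picked out after their values were seen. A change within the sorted cells stays open.

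The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 9139 genes and the highest other split 0, so 1 of the 10 gave as many. For lists the real split called 18, and the highest other called 21, with young replicates 1 and 3 and adult replicate 1 on 1 side. In all, 3 of the 10 splits called as many lists.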
